A study of Homo sapiens with 4 samples.

How the data were processed

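Cap analysis of gene expression (CAGE) was used to measure transcript 5' ends in UM-UC-3, an established human urothelial carcinoma cell line. Per the labels' protocols, cDNA was made from total RNA with random primers, capped molecules were biotinylated and captured on streptavidin beads, and adaptors were ligated to both ends. The labels give 2 wild type samples and 2 cisplatin-resistant samples, and the sample titles set the groups. The resistant cells were grown in medium with 5 µM cisplatin (CDDP); the medium of the wild type cells is not given in the sources used here, so the acquired state and the drug in the culture cannot be told apart in any comparison. Other differences between the groups, such as drift in culture or handling, may be joined to the acquired state and the drug. No label says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

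The deposited table holds CPM values (reads of a gene scaled to the total of its column), 1 column per sample and 13743 genes, each with an Ensembl identifier and a symbol. BWA 0.5.9 and the builds hg19 and mm9 are named, per the submitters' processing notes, with no role for either build. The counting tool, the annotation, the use of strand and the rule that chose the listed genes are not given in the sources used here. Each column of the deposited CPM is scaled to its own total over the genes listed, so the values are relative to the reads in these genes and no further scaling between samples is visible. Because the build behind the identifiers is not settled, no coordinates are given. GENCODE 29 was used only for gene type, for overlaps and for which genes neighbour each other; 99.3% of the tested identifiers matched it. Without known strand use, reads of a gene and of an overlapping or antisense gene may not have been separated. Among the tested genes, 1134 rows in 546 sets shared all 4 values with another row, mostly host genes with small RNAs and overlapping genes.

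Every value lies within 0.0053 CPM of a whole multiple of 1 step per column, of 0.0548 and 0.0551 CPM in the wild type samples and 0.0472 and 0.0562 CPM in the resistant samples. Taking a step as 1 read, the columns hold 18237681 and 18159291 reads for wild type and 21189219 and 17800730 reads for resistant cells. The planned count models were not fitted, because the rounding of the file, 0.005 CPM, exceeds the limit of 0.1 step applied here to accept a column as whole reads in resistant replicate 1; every value there still lies nearest to 1 whole multiple, and the intervals below use the reads so recovered. For groups with few reads, ratios of summed reads are given with exact (Clopper-Pearson) 95% intervals, and a group at 0 is bounded by a floor of 3 reads over the group. In single samples 3 reads equal 0.164 and 0.165 CPM in wild type and 0.142 and 0.169 CPM in resistant cells. These intervals and floors cover counting error only.

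Genes with a mean of at least 1 CPM over the 4 samples were tested (12587 genes; 1156 were left out). The resistant and wild type groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(CPM + 1), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Standard errors are the moderated ones of that model. Before the data were examined, 33 gene lists were fixed, and the 25 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether a list's genes move on balance one way without reference to other genes. With an estimated correlation, camera has only the 2 residual degrees of freedom of the fit, and so little power. Lists with fewer tested members are given as values.

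The genes named were chosen by a rule written before the data were examined: CLSPN, which the series title names; the 12 largest changes in each direction among genes past the threshold with at least 10 CPM in the higher group and no overlap between the groups; and up to 4 members of each list with the smallest adjusted p. Symbols starting with LOC, LINC, MIR or SNOR were passed over. Other genes are named only where the text says so, and some genes that the rule takes are not reported here. The list of cancer-testis antigens held the symbol IMP3, which in this table is another gene than the antigen meant.

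The fit and the list tests were tested on simulated data over 12573 genes, with known changes in 200 genes and a raised list of 30 more. All simulated genes had the same dispersion, 0.00159, estimated from the replicate pairs, and were drawn independently. This estimate is biased low, because the full counting variance was subtracted before the median was rescaled. The recovery and the false calls hold for that spread only, which may be below that of the samples. For the resistant against wild type comparison, 92.5% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold were recovered. Of 235 calls, 7.23% were genes that had not been changed. The raised list was called and 0 of 20 unchanged lists were called. The simulation held neither correlated genes nor changes as widespread as those found here, so it does not test the list calls under such conditions. The samples within a group differed by more than counting noise, with a chi-square per gene of 13.5 for wild type and 5.11 for resistant cells, so neither pair was taken as copies of 1 library; this does not tell separate cultures from separate libraries of 1 culture.

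Alternatives changed the pseudocount, the filter, the scaling between samples (TMM, median-ratio and quantile), the moderation of the spread, a replicate block, the threshold, the list test and the samples, each sample being left out in turn. After the data had been seen, 2 further alternatives were added: rows with identical values counted once, and genes in regional runs left out. Neighbour analyses, permutations and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.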

Results

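CAGE profiles of UM-UC-3 urothelial carcinoma cells were compared between 2 wild type samples and 2 samples of a cisplatin-resistant derivative kept in 5 µM cisplatin. The samples held between 17800730 and 21189219 reads in 13743 genes. Across genes, the wild type samples correlated at Pearson's r = 0.995 and the resistant samples at 0.996, while pairs from different groups lay between 0.952 and 0.953. Genes are not independent replicates, so these values describe the samples only. The first principal component held 90.9% of the variance and separated the groups.

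The series title names CLSPN as a driver of cisplatin resistance. CLSPN encodes claspin, the mediator that links ATR to CHK1 activation at stalled replication forks. CLSPN (ENSG00000092853.14) measured 52.5 ± 5.02 CPM (SD, n = 2) in wild type and 77.1 ± 1.93 CPM (SD, n = 2) in resistant cells, a ratio of 1.47. Its log2 fold change was 0.55 with a standard error of 0.08 (limma, adjusted p = 0.00084), and both resistant samples lay above both wild type samples.

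Resistant and wild type cells differed in 6945 of 12587 tested genes, 4221 higher and 2724 lower in resistant cells. Under TMM, median-ratio and quantile scaling the split was 3508 to 3452, 3486 to 3484 and 3518 to 3415, so the excess of higher genes rests on the scaling of the deposited values. At an absolute log2 fold change of at least 1, 521 genes were higher and 451 lower. Leaving out resistant replicate 1 gave 4285 changed genes and leaving out resistant replicate 2 gave 4279. The groups did not overlap in 9876 genes (78.5%), where chance gives 33.3% for 2 against 2.

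Interferon-stimulated genes rose almost throughout. Of 30 tested members, 29 rose and 0 fell, with a median log2 fold change of 1.73 (camera, adjusted p = 9.66e-14; adjusted p = 0.498 with an estimated correlation). IFI6 (ENSG00000126709.15), a mitochondrial interferon-induced protein, went from 40.3 ± 0.396 to 1709.6 ± 23.3 CPM (SD, n = 2 each), 42.4 times the wild type level (limma, adjusted p = 1.66e-09). ISG15, a ubiquitin-like modifier, went from 61.3 ± 5.60 to 761 ± 13.9 CPM, and IFIT1, which binds RNA lacking a host cap, from 8.93 ± 1.10 to 111 ± 14.0 CPM. OAS1 and OAS3, which sense double-stranded RNA, rose 13.8 and 5.39 times. HERC6 rose from 1.93 ± 0.304 to 26.1 ± 0.75 CPM. ISG20 was the member that did not pass the test.

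NF-kB and cytokine genes fell. Of 14 tested members, 0 rose and 11 fell, with a median log2 fold change of -1.06 (camera, adjusted p = 5.46e-07; adjusted p = 0.426 with an estimated correlation). The neutrophil chemokines CXCL8, CXCL3 and CXCL1 were 20.2, 9.31 and 3.60 times higher in wild type than in resistant cells, and the monocyte chemokine CCL2 was 2.97 times higher. CXCL8 measured 20.2 ± 5.11 CPM in wild type and 1.00 ± 0.0141 CPM in resistant cells (SD, n = 2). Of the preset markers of blood cells the table holds 2: the myeloid marker CD68 read 71.5 and 52.2 CPM in wild type and 28.0 and 29.9 CPM in resistant samples, and the lymphocyte marker CCL5 read 1.15 and 0.99 against 0.66 and 0.79 CPM. Of leukocyte genes listed after the data had been seen, SRGN read 75.7 and 70.8 CPM in wild type and 74.0 and 64.3 CPM in resistant samples, and CORO1A stayed under 1 CPM in each sample.

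Genes of the ATR-CHK1 replication checkpoint rose together. Of 22 tested members, CLSPN among them, 16 rose and 0 fell (median log2 fold change 0.44; camera, adjusted p = 0.00056; adjusted p = 0.426 with an estimated correlation). CDC25A, a phosphatase that CHK1 restrains, rose 2.26 times and ATRIP, the partner of ATR, 1.89 times. DBF4, the activator of the CDC7 kinase, rose 1.82 times and RPA2, a single-stranded DNA binding protein, 1.57 times. ATRIP overlaps TREX1 on the same strand in the annotation, so reads of the genes may not have been separated. Among G2/M and mitosis genes, 22 of 37 rose and 1 fell (camera, adjusted p = 0.00081; adjusted p = 0.518 with an estimated correlation). The proliferation marker MKI67 went from 120.2 ± 1.07 to 233 ± 1.44 CPM (SD, n = 2), and TTK, ECT2 and TOP2A rose 1.76, 1.54 and 1.48 times. Among DNA replication and S phase genes, 23 of 41 rose and 2 fell (camera, adjusted p = 0.028; adjusted p = 0.518 with an estimated correlation). This call ended under quantile normalization (adjusted p = 0.093), without the trend (adjusted p = 0.056) and without resistant replicate 1 (adjusted p = 0.070). The licensing factors CDC6 and ORC6 rose 1.64 and 1.67 times and the ribonucleotide reductase subunit RRM2 rose 1.45 times, whereas the polymerase subunit POLA1 fell by 0.70 on the log2 scale.

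Hypoxia and glycolysis genes fell, 24 of 29 with 0 rising, at a median log2 fold change of -0.72 (camera, adjusted p = 7.44e-12; adjusted p = 0.426 with an estimated correlation). Carbonic anhydrase CA9 went from 32.1 ± 0.488 to 6.03 ± 0.82 CPM, the glycolytic enzyme PGK1 from 728 ± 4.0 to 192 ± 5.88 CPM, the stress-responsive NDRG1 from 50.5 ± 6.10 to 11.2 ± 0.184 CPM and the mitophagy receptor BNIP3 from 559.9 ± 34.0 to 202 ± 7.71 CPM (SD, n = 2 each). Cholesterol synthesis genes also fell, 19 of 22 with 0 rising, at a median of -0.56 (camera, adjusted p = 6.44e-09; adjusted p = 0.518 with an estimated correlation). Squalene epoxidase SQLE was 2.21 times higher in wild type, the farnesyl diphosphate synthase FDPS 2.12 times, FDFT1 1.89 times and MSMO1 1.84 times.

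**Figure D1:**
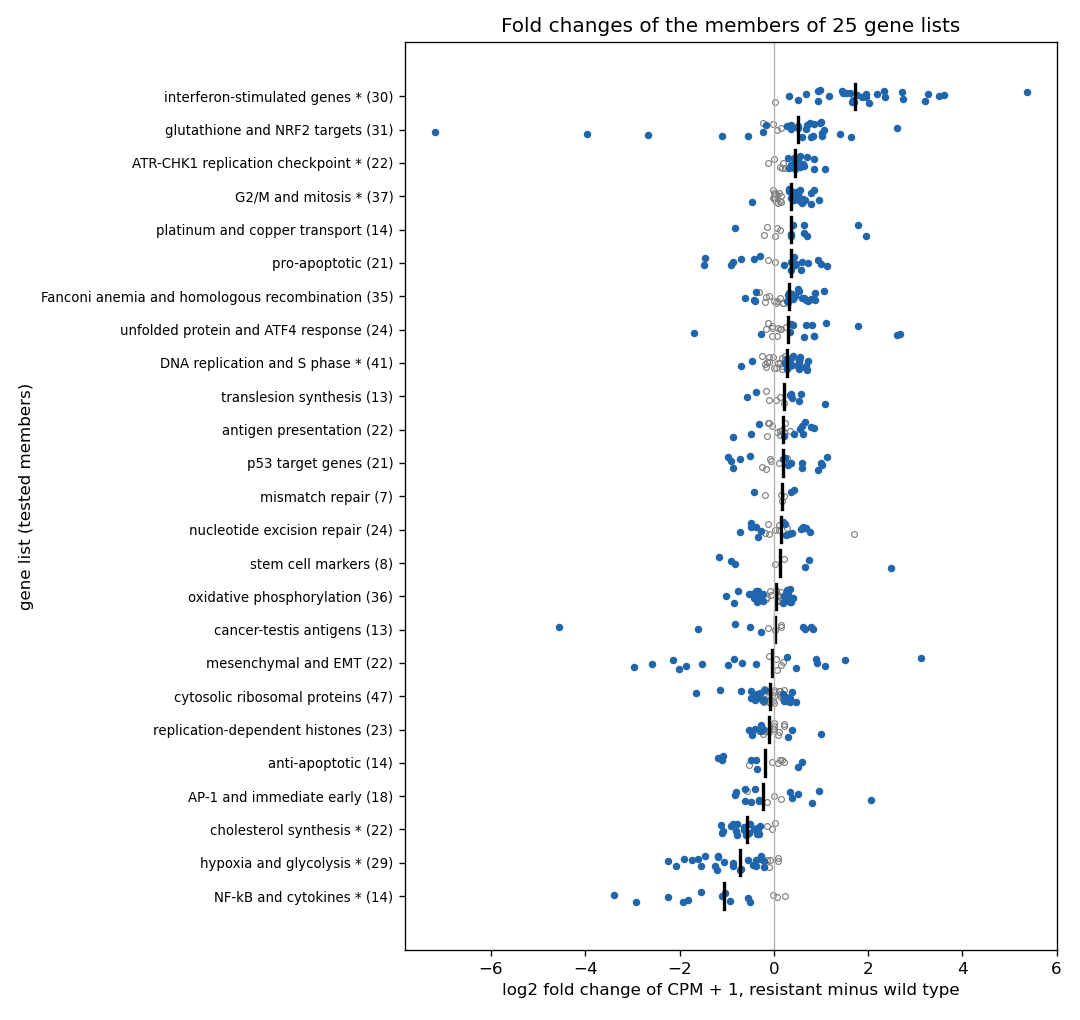
Log2 fold change (CPM + 1, resistant minus wild type) of each tested member of 25 gene lists, one point per gene; filled points passed adjusted p 0.05, open points did not, the black bar is the list's median and a star marks a list called by camera. Interferon-stimulated genes lie at a median of 1.73, and NF-kB and cytokine genes at -1.06.

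The largest decrease among the genes named was that of AKR1C1 (ENSG00000187134.14), an aldo-keto reductase, from 162 ± 4.53 to 0.11 ± 0.0849 CPM (SD, n = 2; limma, adjusted p = 8.59e-09). With 5880 reads in wild type and 4 in resistant cells, the ratio was 1575, with an exact 95% interval of 615 to 5781; it was 959 without resistant replicate 1 and 3423 without resistant replicate 2. Its paralog AKR1C3 went from 22.8 ± 2.11 to 0.51 ± 0.0849 CPM; reads of these close paralogs may be divided between them. The remaining glutathione and NRF2 targets mostly rose, so that the list as a whole had 20 members higher and 7 lower of 31, with a median log2 fold change of 0.51, a mean of 0.07 and an adjusted p just above the threshold (camera, adjusted p = 0.0501); it passed in 11 of 18 alternatives, among them those without wild type replicate 1 (adjusted p = 0.028) and without wild type replicate 2 (0.0258). The cystine importer SLC7A11 rose from 4.20 ± 0.962 to 30.8 ± 0.361 CPM, and the quinone reductase NQO1 from 152 ± 3.73 to 309.7 ± 4.88 CPM.

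Of the unfolded protein and ATF4 response list, 12 of 24 members rose and 2 fell (camera, adjusted p = 0.079). Fry called this list as higher (adjusted p = 0.0167). The amino acid transporter chains SLC7A5 and SLC3A2 rose 6.64 and 3.49 times, and DDIT4, an inhibitor of mTORC1, was 3.29 times higher in wild type. Of platinum and copper transport genes, 8 of 14 rose and 1 fell (camera, adjusted p = 0.157). The list passed as higher in 2 of 18 alternatives, with fry (adjusted p = 0.0036) and with regional runs left out (camera, adjusted p = 0.0456). The exporter ABCC3 rose 5.75 times, from 1.54 ± 0.24 to 8.85 ± 0.834 CPM. ABCB1, the multidrug exporter, had 4 reads in wild type and 109 in resistant cells, a ratio of 25.4 with an exact 95% interval of 9.66 to 95.03; it was 16.9 without wild type replicate 1 and 51.0 without wild type replicate 2. LRRC8A, a subunit of the volume-regulated anion channel, rose 1.6 times, and the copper exporter ATP7A was 2.03 times higher in wild type. ATP7A shares all its values with an overlapping row and overlaps PGK1. Of the metallothionein list, MT1X (which shares its values with an overlapping row) rose 1.56 times and the regulator MTF1 1.83 times, and MT2A read 1911 ± 109 and 2075 ± 69.3 CPM, a difference that did not pass (adjusted p = 0.23).

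Repair lists changed in both directions and none was called by camera, except Fanconi anemia and homologous recombination genes when genes in regional runs were left out (adjusted p = 0.0356; 0.0095 to 0.518 over the alternatives of that list). Fry called that list (adjusted p = 0.0095) and translesion synthesis (adjusted p = 0.0227). In nucleotide excision repair 10 of 24 members rose and 6 fell (adjusted p = 0.851); XPA rose 1.62 times and ERCC8 1.77 times, while ERCC1 was 1.30 times and CETN2 1.41 times higher in wild type. Among Fanconi anemia and homologous recombination genes 19 of 35 rose and 4 fell (adjusted p = 0.12), with UBE2T up 1.85, PALB2 1.90, RBBP8 1.77 and BRCA1 1.53 times. RBBP8 shares its values with a microRNA row. In mismatch repair 2 of 7 rose and 1 fell (adjusted p = 0.851). MSH6 was 1.35 times higher in wild type, and PMS2 and MLH3 rose 1.30 and 1.44 times. PMS2 lost its call in 4 alternatives and MLH3 in 5, among them the fits without resistant replicate 1 (adjusted p = 0.171 and 0.213). In translesion synthesis 6 of 13 rose and 2 fell (adjusted p = 0.597), with REV1 up 2.26, MAD2L2 1.5 and HLTF 1.28 times and UBE2A 1.5 times higher in wild type.

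Apoptosis genes were divided. Of p53 targets, 10 of 21 rose and 5 fell (camera, adjusted p = 0.851), while fry called the list as higher (adjusted p = 0.0271). BAX rose 2.01, FAS 2.29 and PMAIP1 1.99 times, and TP53I3 was 2.07 times higher in wild type. Of anti-apoptotic genes, 2 of 14 rose and 6 fell (camera, adjusted p = 0.157), and fry called them as lower (adjusted p = 0.0037). TNFRSF10D, BCL2L1 and BIRC3 were 2.35, 2.13 and 2.19 times higher in wild type and BIRC5 rose 1.43 times. Of pro-apoptotic genes, 12 of 21 rose and 7 fell (adjusted p = 0.851), BNIP3L being 2.81 times higher in wild type.

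Markers of cell state changed in both directions. Only 4 of 21 luminal, 4 of 22 basal and squamous and 8 of 20 stem cell markers were tested. In the mesenchymal and EMT list 7 of 22 rose and 10 fell (adjusted p = 0.12); the list passed as lower in 3 of 18 alternatives, at a mean of at least 5 CPM (adjusted p = 0.0093), with fry (0.0271) and with regional runs left out (0.0456), and its median relative to all genes, -0.12, lay between -0.038 and -0.629 over the alternatives. The matrix protease MMP14 went from 199 ± 7.91 to 48.4 ± 0.658 CPM, LOXL2 was 2.90 times and COL6A2 11.1 times higher in wild type, and POSTN, with 0 reads in wild type and 305 in resistant cells, was at least 94.9-fold higher against a floor of 3 reads over the group. The luminal keratins KRT18 and KRT8, neighbours that overlap in the annotation, were 3.5 and 2.11 times higher in wild type, while KRT7 rose 1.84 times and ERBB2 read 23.8 ± 3.04 and 21.6 ± 1.20 CPM (adjusted p = 0.35). Of basal markers, CD44 and ITGA6 were 2.28 and 1.89 times higher in wild type, EGFR rose 1.47 times and LAMB3 read 9.34 ± 0.127 and 10.2 ± 0.339 CPM (adjusted p = 0.43). In the stem cell list 3 of 8 rose and 3 fell (camera, adjusted p = 0.851). Its median was 0.13 and its mean 0.15, but camera ranked it below other genes, while fry called it as higher (adjusted p = 0.0065). ALDH1A1, a retinaldehyde dehydrogenase, rose 6.24 times and SOX9 1.6 times. The fibroblast and muscle marker ACTA2 read 0.82 and 0.88 CPM in wild type and 1.51 and 1.91 CPM in resistant samples. ACTA2 overlaps FAS, which also rose, on the opposite strand in the annotation, so their reads may not have been separated. COL1A1 and COL3A1 stayed under 0.5 CPM in each sample. AFP read between 0.11 and 1.16 CPM, and none of the 10 endothelial markers was in the table.

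Antigen presentation genes rose in 8 of 22 cases and fell in 3 (adjusted p = 0.438). B2M, the light chain of HLA class I, went from 579 ± 23.7 to 883 ± 1.15 CPM, HLA-C rose 1.47 times and TAP2, which shares its values with an overlapping row, 1.83 times, and the chaperone PDIA3 was 1.41 times higher in wild type. Of cancer-testis antigens 4 of 13 rose and 5 fell (camera, adjusted p = 0.514, median 0.02, mean -0.36), while fry called the list as lower (adjusted p = 0.0307). MAGEC2 went from 54.5 ± 3.02 to 1.36 ± 0.339 CPM, MAGEA4 was 1.79 times higher in wild type, and SPANXB1, with 74 reads in wild type and 0 in resistant cells, was at least 26.4-fold lower against a floor of 3 reads over the group. In the AP-1 and immediate early list 6 of 18 rose and 8 fell (adjusted p = 0.377; median -0.23, mean 0.01): EGR1 rose 5.36 and DUSP5 1.96 times, and JUN and DUSP1 were 1.53 and 1.55 times higher in wild type.

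Oxidative phosphorylation genes rose in 11 and fell in 13 of 36 cases (camera, adjusted p = 0.217, median 0.04, mean -0.08), and fry called them as lower (adjusted p = 0.0412). COX6C, NDUFA1 and COX7B were 1.80, 2.04 and 1.70 times higher in wild type. Of cytosolic ribosomal proteins 11 of 47 rose and 16 fell (adjusted p = 0.12); the list passed as lower without wild type replicate 1 (adjusted p = 0.0077). RPS4X and RPL7 were 2.23 and 1.63 times higher in wild type and RPS18 rose 1.31 times, a call that ended without resistant replicate 1 (adjusted p = 0.054). RPS6 went from 2879 ± 405 CPM in wild type to 965 ± 453 CPM in resistant cells (SD, n = 2 each), where the samples read 1285 and 645 CPM, and lost its call under the robust trend (adjusted p = 0.094). Of replication-dependent histones 3 of 23 rose and 6 fell (adjusted p = 0.197). H2AW rose 2.02 and H4-16 1.30 times, and H2BC5 and H4C3 were 1.45 and 1.37 times higher in wild type, the latter not past the threshold without resistant replicate 1 (adjusted p = 0.063). Adjusted over the list alone, the counts of all tested lists were those given, except 24 rising in DNA replication, 21 rising in glutathione and NRF2 targets, 7 falling in nucleotide excision repair and in anti-apoptotic genes, 9 falling in AP-1 genes, and 12 rising and 17 falling in ribosomal proteins.

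Outside the lists, several genes rose from a low level, which for PDE1A and AC104823.1 lay near the detection floor, to a clear signal. PDE1A, a calmodulin-dependent phosphodiesterase, had 1 read in wild type and 752 in resistant cells, a ratio of 702 with an exact 95% interval of 126 to 27760. The transcript AC067945.2, which lies on the opposite strand of STAT4, went from 0.825 ± 0.233 to 53.6 ± 3.37 CPM, DSEL from 2.36 ± 0.226 to 48.2 ± 4.59 CPM and CPED1 from 2.50 ± 0.0424 to 40.3 ± 4.74 CPM. AC104823.1, EYA4, a transcriptional coactivator and phosphatase, and AP1M2, a clathrin adaptor subunit, rose 145, 43.1 and 39.2 times by summed reads, with exact 95% intervals of 49.2 to 704, 23.9 to 86.9 and 21.1 to 82.4. Among the decreases, CPA4 (1069 reads against 2), RGS4 (1081 against 3), SIRLNT (1023 against 5) and AL035446.2 (900 against 1) had ratios of 573, 386, 219 and 964 of wild type to resistant. The exact 95% intervals of these ratios had lower ends of 158, 132, 93.6 and 173. The calcium-binding protein S100A6 went from 861 ± 208 to 38.7 ± 0.431 CPM, and TMEM132D-AS1 and MARCHF3 were 35.0 and 39.5 times higher in wild type. COL4A2 and C11orf96, with 11 and 16 reads in resistant cells, were 68.8 and 50.6 times higher in wild type by summed reads (exact 95% intervals 38.2 to 138 and 31.0 to 89.0). COL4A2 overlaps COL4A1 in the annotation. Several ratios of summed reads moved by over 1.5 times with 1 sample left out, where a group then at 0 is set at 3 reads. Without wild type replicate 1, PDE1A stood at 350 and AC104823.1 at 72.2; without wild type replicate 2, they were at least 117-fold and 72.5-fold higher and EYA4 stood at 79.2. Without resistant replicate 1, COL4A2 and C11orf96 stood at 38.4 and 33.6, and CPA4, RGS4 and AL035446.2 were at least 174-fold, 176-fold and 147-fold lower; without resistant replicate 2, these 5 ratios were 205.5, 88.0, 311, 210 and 524.

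**Figure D2:**
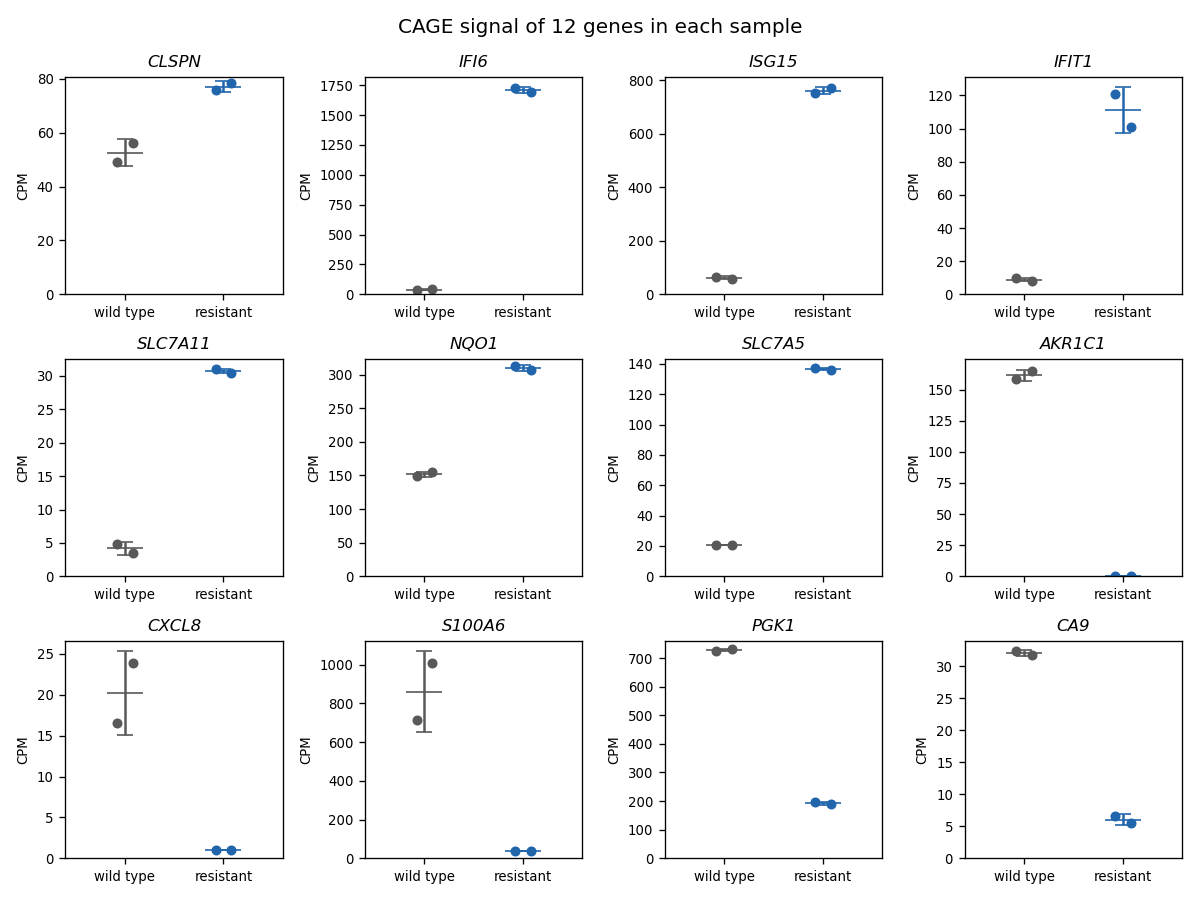
CPM of 12 genes in each of the 4 samples; points are samples, the horizontal mark is the group mean and the bar is the SD (n = 2), with the vertical axis starting at 0. IFI6 reads 40.3 CPM on average in wild type and 1709.6 CPM in resistant cells, and AKR1C1 162 and 0.11 CPM.

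Several of the genes named lie in runs of neighbouring genes that moved together between the groups. Some changed far more than their run, such as MAGEC2 (log2 fold change -4.56), TMEM132D-AS1 (-4.34), AC067945.2 (4.91) and AC104823.1 (3.58). Others, such as UBE2A (-0.58) and CETN2 (-0.49), lay close to the median of theirs. PGK1, ATP7A, RPS4X, COX7B, NDUFA1, UBE2A, CETN2, MAGEC2, MAGEA4 and SPANXB1 lie in a run of 222 tested genes with a median log2 fold change of -0.52. COX6C, SQLE and NDRG1 lie in a run of 144 genes at -0.42, BCL2L1 in a run of 75 genes at -0.47, POLA1 in a run of 51 genes at -0.42 and TMEM132D-AS1 in a run of 33 genes at -0.44. AC067945.2 and AC104823.1 lie in a run of 29 genes at 0.61, H2AW in a run of 100 genes at 0.82, PMS2 in a run of 37 genes at 0.58, LRRC8A in a run of 123 genes at 0.58 and ALDH1A1 in a run of 27 genes at 0.52.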

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

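The alternatives with identical rows counted once and with genes in regional runs left out were chosen after seeing the data. No gene called in the deposited-scale comparison was called in the opposite direction in any of the 15 alternative fits of all genes, and CLSPN passed the threshold in all 15 alternatives, with log2 fold changes from 0.43 to 0.64 and adjusted p from 0.00013 to 0.023. Of 123 named genes, 116 stayed on their side of the threshold in every alternative that tested them, 5 lost their call in at least 1 (MLH3, PMS2, RPS6, H4C3 and RPS18) and 2 gained it, MT2A among them. ABCB1, ATP7A, POSTN, SPANXB1 and MLH3 were tested in 14 of the 15 alternatives. Leaving out resistant replicate 1 ended the calls of H4C3 (adjusted p = 0.063), RPS18 (0.054), PMS2 (0.171) and MLH3 (0.213). The number of changed genes lay between 4279 and 6790 when 1 sample was left out, with 2556 to 4316 higher and 1636 to 2787 lower; it was 4285 without resistant replicate 1 and 4279 without resistant replicate 2. The lone sample left in a group is assumed to vary like the other group, and fewer samples leave fewer degrees of freedom. An absolute log2 fold change of at least 1 left 972 genes, 521 higher and 451 lower, by construction. Same-numbered samples did not deviate together (r = -0.079), which does not exclude another pairing or a shared batch. With the replicate number as a block 7098 genes were called. The planned count tests on recovered reads were not run.

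Of the lists, 7 were called in the main comparison, 0 with an estimated correlation and 17 with fry, which does not compare a list with other genes. The test with an estimated correlation had only 2 residual degrees of freedom, so its lack of calls cannot decide for or against a list. Of the 25 lists, 10 had an unadjusted p under 0.05 in the main comparison. With genes in regional runs left out 12 lists were called. That alternative removes whole runs, including members that moved against their run. The runs were found from the same fold changes, so the calls of that alternative are not independent of them. Lists that were not called in the main comparison changed direction as follows, and the cause was not tested. At a mean of at least 5 CPM, relative medians were 0.0090 for nucleotide excision repair, 0.0659 for mismatch repair and 0.0853 for p53 targets, with the test's direction down. Under quantile normalization they were 0.0366 and 0.0702 for nucleotide excision repair and mismatch repair. With 1 sample left out, the relative median of mismatch repair lay between 0.0374 (without wild type replicate 1, where its direction turned) and 0.210, and that of the stem cell list between -0.0632 and 0.146 (without resistant replicate 1, where its direction turned). With fry the mean was 0.154 for the stem cell list, then called as higher (adjusted p = 0.0065), and 0.0073 for AP-1 genes. With regional runs left out, the relative median of the stem cell list was -0.914 on 5 members, its direction down as in the main comparison. With regional runs left out, mismatch repair stood at 0.0856, pro-apoptotic genes at 0.194 and cancer-testis antigens, then called as higher (adjusted p = 0.046) on 6 members, at 0.551. Fry called the cancer-testis antigens the other way, as lower (adjusted p = 0.0307, mean -0.357). The gap between within-group and between-group correlation, 0.042 in the main setting, was 0.0534 with a pseudocount of 0.25, 0.0323 with 4 and 0.0520 at a mean of at least 5 CPM. Values near 3 reads cannot show a difference at this depth.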

Other observations

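The tests on reads shared between AKR1C paralogs, on NRF2 activity and on blood cells, as well as the gene families and the genes near the floor below, were chosen only after the result was seen. Of 10 tested genes whose symbols start with COL and a number, 5 fell and 2 rose, with a median log2 fold change of -1.29 (camera, adjusted p = 0.384). COL4A1, COL6A1 and COL13A1, chosen after their values were seen, measured 7.31, 12.3 and 26.5 CPM in wild type and 0.045, 1.23 and 3.64 CPM in resistant cells. HAS2, the main hyaluronan synthase of many mesenchymal cells, and the matrix protease ADAMTS12 measured 12.6 ± 0.311 and 10.7 ± 0.771 CPM in wild type (SD, n = 2) and were at 0 in both resistant samples; HAS2 lies in a run of 144 genes at a median log2 fold change of -0.42. In all, 8 genes were at 10 CPM or more in both wild type samples and at 3 reads or fewer in each resistant sample, and 2 genes, PDE1A and AC104823.1, showed the opposite.

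Of 11 tested PARP genes, which encode ADP-ribosyltransferases, 8 rose and 1 fell, with a median of 0.78. PARP9 and PARP14, both interferon-inducible, went from 5.14 to 17.1 CPM and from 26.2 to 47.0 CPM, and PARP1, which acts at DNA breaks, from 106.7 to 191.6 CPM. PARP1 lies in the higher run from INTS7 to TARBP1 given below, and its log2 fold change of 0.84 is close to the median of that run, 0.82. Of the anaphase-promoting complex genes 8 of 10 rose and 0 fell. Under TMM, median-ratio and quantile scaling the counts for collagen and PARP genes were the same, and those for the anaphase-promoting complex were 6 rising and 1 falling. Among 140 symbol families with at least 10 tested genes, 0 passed camera after adjustment (adjusted p = 0.384 for collagens and for PARP genes), 12 had an unadjusted p under 0.05, and 0 passed with an estimated correlation.

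Fold changes of neighbouring genes went together. Adjacent tested genes correlated at r = 0.274 across 11930 pairs, and runs of neighbours formed 10 higher and 9 lower stretches that held 1244 of 11953 ordered genes, among them 100 genes from INTS7 to TARBP1 at a median log2 fold change of 0.82 and 222 genes from FAM104B to IKBKG at -0.52. Overlapping genes counted with the same reads are argued against, since pairs over 10 kb apart still correlated at 0.232 (permutation p = 0.0005, the smallest that 2000 permutations can give). Removing the trend on GC content and length of the longest annotated transcript left 0.993 of the correlation, which argues against a bias by these measures. The GC content of the captured transcript ends was not examined, so a bias by it stays open. Genes 20 tested genes apart correlated at 0.142 (permutation p = 0.0005), while at that distance the differences between replicates correlated at -0.0090 and -0.0033 (permutation p = 0.83 and 0.63), against 0.0664 and 0.0504 for adjacent genes, as gains and losses of chromosome segments would give. Such gains and losses are therefore a candidate explanation, as a hypothesis, but DNA copy number was not analysed here, and regional control of transcription without them stays open.

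AKR1C genes fell while other glutathione and NRF2 targets rose. Reads shared between the paralogs stay open for the fall of AKR1C3: the ratio of AKR1C1 to AKR1C3 was 7.10 (95% interval 6.60 to 7.65) in wild type and 0.2 (0.050 to 0.597) in resistant cells, a difference of 35.5 times, but AKR1C1 reads placed on AKR1C3 would be lost with AKR1C1 and give the same shift. Weaker NRF2 activity would lower the other members of the list as well. The median of the 27 other members lay 0.601 above that of all genes, which argues against a general weakening across them. Of the whole list of 31, 20 members rose and 7 fell. The test restates the pattern and so adds no independent evidence, and NRF2 activity itself was not measured. Loss of the chromosome segment around the AKR1C genes cannot be told apart from control of these genes alone: the 12 nearest tested genes had a median log2 fold change of -0.333, between the values set for either, with 9 of them lower, TUBAL3 (log2 fold change -2.17), LASTR (-1.51) and ASB13 (-1.06) the most, and 1 higher, TASOR2 (0.68). A small deletion could leave the outer neighbours in place, and a test of DNA was not analysed here.

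Interferon-stimulated genes rose while NF-kB and cytokine genes fell. Scaling between samples is argued against, since a factor common to all genes of a sample moves both lists the same way. The 3 other scalings moved the median of either list by at most 0.088. The median of all tested genes moved by -0.083 (TMM), -0.086 (median-ratio) and -0.074 (quantile), so these fits add little to that argument. A few loci with many members are argued against too, since 1 gene for each of the 22 loci gave 1.05 times the median over all 30 members. Cells of the blood lineages in the resistant cultures cannot be told apart from a change in the line itself: the 2 markers in the table had a median log2 ratio of -0.666, but CD68 has a high baseline in the line and CCL5, which the list of cytokines also holds, lies near 1 CPM, so neither excludes a small share of such cells; the rule that sets such markers aside was added when their values were known, and without it the test would have argued against these cells. As the whole cause of the interferon rise, such cells would have to bring a gain in leukocyte transcripts too. Only 4 of the 38 listed are in the table, and their median gain was -2.23 CPM. The interferon-stimulated genes gained 17.6 CPM by their median, a ratio of -0.126. The mean of each of the 4 transcripts was lower in resistant cells, though the groups overlapped for SRGN. For these 4 transcripts, the values argue against blood cells as the whole cause, while a small share stays open. The test as written needs 5 transcripts and so gave no verdict, and the values of CD68 and CCL5 were known when it was written. Whether the change belongs to the acquired state or to cisplatin in the medium stays open, as the design joins them. Other differences between the groups, such as drift in culture or handling, may be joined to them too.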
